A study of Homo sapiens with 16 samples.

How the data were processed

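RNA sequencing measured transcript levels in 16 libraries from 4 liver cancer cell lines, each grown under 4 treatments for 24 h: control, gefitinib, lenvatinib or both drugs. Every line contributed 1 library to each treatment, and the labels number no replicates, so the line served as the replicate: replicate 1 is SNU449, 2 is JHH1, 3 is Huh6 and 4 is SNU182. Groups came from the treatment label of each sample. Per the labels' protocols, RNA was lysed in RLT buffer and libraries followed a standard Illumina protocol. The control is called untreated in one label and vehicle (DMSO) in the treatment protocol. Doses read 2.5 mM gefitinib and 5 mM lenvatinib; these are far above usual culture doses, the unit cannot be settled here, and the doses in the combination are not given in the sources used here.

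The authors deposited a table of raw read counts per Ensembl gene with 1 column per library, and 32651 genes have a line in it. Per the submitters' processing notes, TopHat2 2.1, Bowtie 1.1 and HTSeq were used with genome build hg38; the HTSeq version, the strand setting and the annotation release are not given in the sources used here. Reads of antisense or overlapping partners, and of near-identical copies such as pseudogenes of chaperone and ribosomal protein genes, can therefore not be assigned with certainty. Coordinates are those of the authors' table. A second table the authors deposited holds log2 values, and each was found to equal log2 of 1 plus the count scaled to a fixed total per library; it entered 1 alternative only. Total counts per library ran from 11321037 to 17664695, genes with at least 1 count from 19251 to 22173, mitochondrial transcripts from 4.30% to 10.2% of counts, and the 10 most abundant genes from 5.38% to 9.79%. These totals set the counting precision of each library.

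Counts were analysed in R 4.3.3 with edgeR 4.0.16. The filter filterByExpr (minimum count 10, by treatment) left 16566 genes, libraries were scaled by TMM, and a quasi-likelihood model held the cell line (as a block) and the treatment, over all 16 libraries with 9 residual degrees of freedom. All tests are two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and 0.05 was the threshold. Fitted log2 changes are given ± their standard error, the absolute change divided by the square root of its F value. This error comes from the model over all 16 libraries and is not the spread of the 4 line values. Lines with more counts weigh more, so for a gene expressed in 1 line the change and its error rest mainly on that line. The median biological coefficient of variation was 0.177. Same-line libraries deviated together from their treatment means (r of 0.915 to 0.980 over 24 pairs, against -0.458 to -0.110 over 96 pairs from different lines), and all 16 libraries correlated best with their own line. Subtracting treatment means itself pushes the values between lines below 0, and this check cannot detect treatment labels exchanged within a line. With 1 library per line and treatment, p-values measure only the spread between these samples. The comparisons were each drug and the combination against control, the combination against each drug, gefitinib against lenvatinib, and the departure of the combination from the sum of both single-drug log2 changes. A further model gave each line its own gefitinib and lenvatinib effect, taking the drugs as additive, with 4 residual degrees of freedom. Each of its values per line has that 1 line as n. Changes within 1 line are differences of log2 CPM with a prior count of 2, carry no test, and count as 2-fold from a difference of 1. Correlations across genes used genes with a mean log2 CPM of at least 3 where stated; genes are not independent replicates.

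The 31 gene lists were fixed before the data were examined, as were the comparisons, the main tests, most alternatives and the rule for named genes. They cover ERK output, immediate early genes, ErbB receptors with ligands and feedback genes, lenvatinib target receptors and ligands, the ERK5 axis, DNA replication, mitosis, cell cycle brakes, the BCL2 family, FOXO targets, p53 targets, cholesterol synthesis, fatty acid synthesis, lysosome and autophagy, ATF4 targets, hypoxia and glycolysis, interferon response, antigen presentation, NF-kB cytokines, YAP targets, mesenchymal genes, hepatocyte genes, AhR targets, NRF2 targets, heat shock, ribosome biogenesis, mitochondrial transcripts, replication-dependent histones, and markers of endothelial cells, leukocytes, and stellate cells and fibroblasts. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with a correlation estimated per list, and with fry, each adjusted over the 31 lists. Single members were also counted as adjusted over the list alone. The named genes are, per comparison, up to 10 higher and 10 lower genes with the largest change among those past the threshold with a mean log2 CPM of at least 1 and the same sign in all 4 lines, leaving out clone names (with none past the threshold, the 5 smallest p). They also include up to 4 members of each list described, or 2 as values where none passed, and EGFR, its family and feedback genes, PAK2, MAPK7 and the receptors of lenvatinib throughout. For differences between lines they are up to 10 genes with the smallest adjusted p. Some genes that meet these rules are not reported here by name.

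The test was checked on simulated counts. In the simulation of the comparisons each change was the same in all 4 lines, and no drug effect differed between lines. Where real effects differ between lines, these recovery and false-call numbers need not hold. For the combination against control it recovered 8, 37, 48 and 49 of 50, 50, 50 and 49 genes changed 1.5-fold, 2-fold, 4-fold and 8-fold, among 16383 genes. For the combination against gefitinib it recovered 13, 33, 50 and 49, for the departure from additivity 8, 20, 41 and 48, and 3 comparisons simulated without change gave 0 calls. Unchanged genes made up 10 of 152 calls for the combination against control, 0 of 148 against lenvatinib, 10 of 155 against gefitinib and 3 of 120 for the departure from additivity. A further simulation let gefitinib change genes in Huh6 alone. There the test for a gefitinib effect that differs between lines recovered 1, 13, 31 and 39 of 50 genes at 1.5-fold, 2-fold, 4-fold and 8-fold. Of its 89 calls, 5 were unchanged genes. Alternatives were no cell line block, DESeq2 1.42.0 size factors, no filter on low counts, the DESeq2 Wald test (also without that filter), limma-voom, limma-trend on the deposited log2 values, the pair of groups alone, and leaving out each library or each line. Chosen after seeing the data were a restriction to 11224 genes reaching 1 CPM in all 4 lines, leaving out both single-drug libraries of SNU449, and exchanging their labels. Where a group lost a library, its remaining libraries are assumed to vary like those of the other groups. Gene coding status came from the authors' table, and no reads were realigned.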

Results

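The data are RNA sequencing counts from 16 cultures of 4 liver cancer cell lines, each grown for 24 h as a control or with gefitinib, lenvatinib or both drugs. SNU449, JHH1 and SNU182 are hepatocellular carcinoma lines, and Huh6 is usually described as a hepatoblastoma line. Gefitinib inhibits the kinase of the epidermal growth factor receptor (EGFR). Lenvatinib inhibits several receptor kinases, among them the VEGF and FGF receptors, PDGFRA, KIT and RET, and is used against hepatocellular carcinoma. The design asks what each drug does alone and whether their combination does more, a question raised by the proposal that EGFR signalling limits the response of liver cancer cells to lenvatinib. Each treatment had 4 libraries, 1 per line. Total counts in SNU449 were 16969032 for control, 17664695 for gefitinib, 13383045 for lenvatinib and 15033510 for the combination. In JHH1 they were 14789083, 13505546, 11321037 and 13869541 in the same order. In Huh6 they were 14508669, 15002965, 12059593 and 14573303, and in SNU182 13673061, 12598481, 13366947 and 13154470.

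With both drugs together, several genes that the ERK kinases switch on as their own feedback were among the largest decreases. ETV4, a PEA3 family transcription factor (ENSG00000175832, chromosome 17, 43527844 to 43579620 of hg38), fell by 4.61 ± 1.08 on the log2 scale against control (adjusted p = 0.0107), with differences of -5.65 in SNU449, -3.78 in JHH1, -7.30 in Huh6 and -2.75 in SNU182. DUSP6, the phosphatase that inactivates ERK (ENSG00000139318, chromosome 12, 89347232 to 89353271), fell by 4.07 ± 0.80 (adjusted p = 0.00626). The feedback inhibitor SPRY4 (ENSG00000187678, chromosome 5, 142310427 to 142326455) fell by 4.06 ± 1.1 and ETV5 fell by 3.38 ± 0.99. FOSL1, an AP-1 subunit (ENSG00000175592, chromosome 11, 65892049 to 65900573), fell by 2.72 ± 0.37 and was nearly even across lines, from -2.94 in SNU449 to -2.27 in JHH1. The other largest decreases with the same sign in all 4 lines were EMP1 (-2.82 ± 0.83), the Gs-coupled receptor GPR3 (-2.81 ± 0.70), MYEOV (-2.73 ± 0.68), the neutrophil chemokine CXCL8 (-2.67 ± 0.73) and the ERK phosphatase DUSP4 (-2.58 ± 0.78). The largest increases with the same sign in all 4 lines were the ascorbate transporter SLC23A1 (4.44 ± 0.88) and SERPINF2, the liver-secreted plasmin inhibitor (4.23 ± 0.78; ENSG00000167711, chromosome 17, 1742836 to 1755268). The small heat shock protein CRYAB followed at 3.13 ± 0.81, the interferon-induced IFIT1 at 2.98 ± 0.46 and TMEM140 at 2.96 ± 0.51. CIDEB, a lipid droplet protein, rose by 2.92 ± 0.85, the xenobiotic monooxygenase CYP1A1 by 2.80 ± 0.59, the sialyltransferase ST6GALNAC2 by 2.80 ± 0.57, the orphan receptor GPR146 by 2.71 ± 0.79 and the endothelin EDN2 by 2.65 ± 0.56. CIDEB rested on Huh6, where it was 4.39 higher, against 0.07 to 0.61 in the other lines.

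In total 4848 of 16566 genes differed between combination and control in edgeR's quasi-likelihood test, 2805 higher and 2043 lower, and 992 of these were at least 2-fold higher and 328 at least 2-fold lower. Among genes reaching 1 CPM in all 4 lines these calls were nearly even, 1995 higher and 1877 lower. Without the Huh6 combination library 1638 genes were called higher and 1675 lower. Of the called genes, 82.2% had the same sign in all 4 lines, against 35.1% of all tested genes. The test itself favours genes on which the lines agree, so part of this contrast follows from the selection. The count was 2827 without the SNU449 control, 2333 without the Huh6 control, 2417 without SNU449 and 1701 without JHH1, and 0 without the cell line block (752 at an unadjusted p under 0.05). A fit of these groups alone called 1 gene, with 4053 of 14314 at an unadjusted p under 0.05 (7077 of 16566 in the main fit). The count of 4848 thus rests on the spread shared by all 16 libraries. Of the named genes called here, 54 of 85 kept the call without SNU449, 50 of 83 without JHH1, 66 of 83 without Huh6 and 67 of 84 without SNU182.

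Most genes of the ERK output, ribosome biogenesis, DNA replication and mitosis lists fell. Of 17 tested ERK output genes 14 fell, 14 adjusted over the list alone (camera adjusted p = 1.15e-08, adjusted p = 0.271 with an estimated correlation). The list's median differed from control by -2.94 in SNU449, -1.55 in JHH1, -2.68 in Huh6 and -0.84 in SNU182. All 19 genes of ribosome biogenesis fell, also adjusted over the list alone, led by NOP16 (-1.85 ± 0.36), RRS1 (-1.55 ± 0.31) and the spermidine synthase SRM (-1.50 ± 0.32). Their camera adjusted p was 3.62e-12, and adjusted p = 0.283 with an estimated correlation. Of 25 DNA replication genes 17 fell (19 adjusted over the list alone), among them the replication factor MCM10 (-1.08 ± 0.24), the ribonucleotide reductase subunit RRM2 (-1.01 ± 0.16) and the helicase cofactor CDC45 (-0.93 ± 0.20). Of 20 mitosis genes 15 fell (16 adjusted over the list alone), including the anaphase activator CDC20 (-0.75 ± 0.08), the kinase PLK1 (-0.70 ± 0.11) and cyclin CCNA2 (-0.65 ± 0.10). Both lists had a camera adjusted p of 1.01e-09, with adjusted p = 0.376 for DNA replication and adjusted p = 0.271 for mitosis with an estimated correlation. Of 14 NF-kB cytokine genes 5 fell and 1 rose, the same numbers adjusted over the list alone, with the monocyte chemokine CCL2 at -2.15 ± 0.30 and IL11 at -1.96 ± 0.55. That list's camera adjusted p was 0.0122 (adjusted p = 0.218 with an estimated correlation), and 0.0794 without SNU182.

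**Figure D1:**
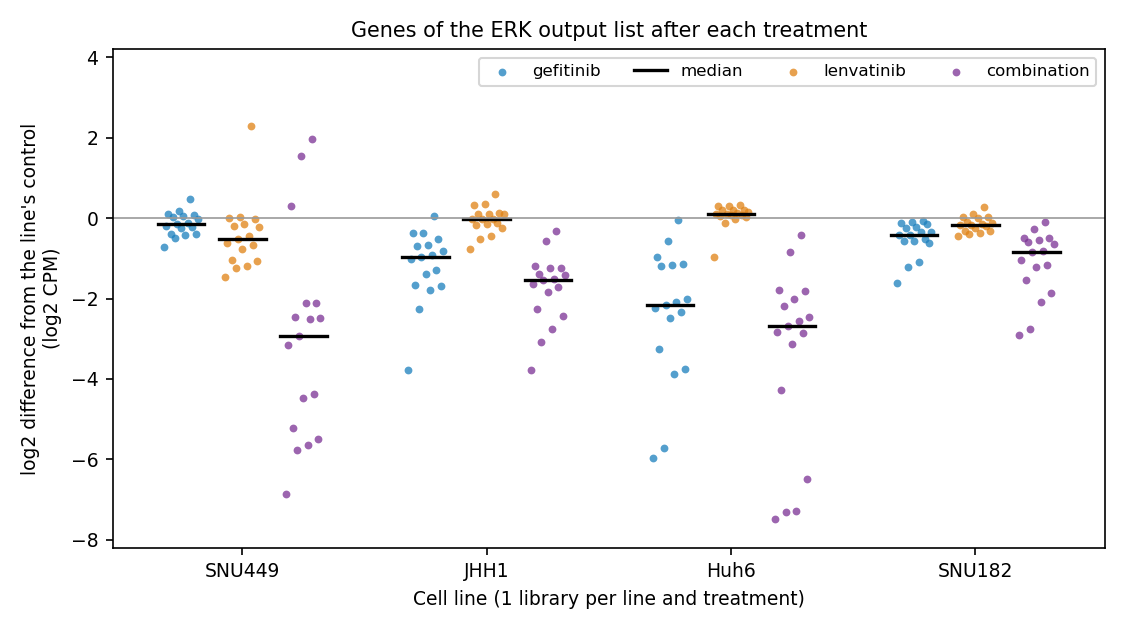
Log2 difference from the line's own control for each of the 17 genes of the ERK output list (points) after gefitinib, lenvatinib or both, in each cell line, with black bars at the medians. The combination medians lie at -2.94, -1.55, -2.68 and -0.84, each below the gefitinib and the lenvatinib median of the same line.

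Many genes that restrain the cell cycle or serve lysosomes rose, and 8 of 19 hepatocyte genes did, with the highest median in Huh6. Of 11 cell cycle brakes 8 rose (9 adjusted over the list alone), with the atypical cyclin CCNG2 at 1.75 ± 0.49, the thioredoxin inhibitor TXNIP at 1.29 ± 0.24 and the CDK4/6 inhibitor CDKN2C at 1.18 ± 0.33. Of 15 FOXO targets 11 rose (12 adjusted over the list alone), including KLHL24 (2.14 ± 0.33), the PI3K inhibitor PIK3IP1 (2.03 ± 0.55) and CITED2 (1.30 ± 0.23). Camera gave adjusted p-values of 0.00242 and 0.00048 for these lists, and adjusted p = 0.271 and 0.376 with an estimated correlation. Of 15 lysosome and autophagy genes 10 rose (12 adjusted over the list alone), among them GPNMB (1.46 ± 0.34), the autophagy kinase ULK1 (1.40 ± 0.31) and cathepsin CTSD (0.89 ± 0.18). Their camera adjusted p was 0.000167 (adjusted p = 0.271 with an estimated correlation). Of 19 hepatocyte genes 8 rose (10 adjusted over the list alone), with apolipoprotein APOC3 at 3.17 ± 0.42 and the fibrinogen chains FGG and FGA at 2.82 ± 0.60 and 2.70 ± 0.43. The hepatocyte medians were 1.39 in Huh6, 0.42 in SNU449, 0.04 in JHH1 and 0.08 in SNU182, and the list's camera adjusted p of 0.000149 became 0.189 without Huh6 (adjusted p = 0.271 with an estimated correlation). Of 5 AhR targets 4 rose (5 adjusted over the list alone), with CYP1B1 at 2.23 ± 0.61 and the AhR repressor AHRR at 1.01 ± 0.15 beside CYP1A1 (camera adjusted p = 0.00303, adjusted p = 0.218 with an estimated correlation). CYP1B1 was 3.55 higher in SNU449 and 0.04, 0.00 and 0.58 higher in JHH1, Huh6 and SNU182.

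**Figure D2:**
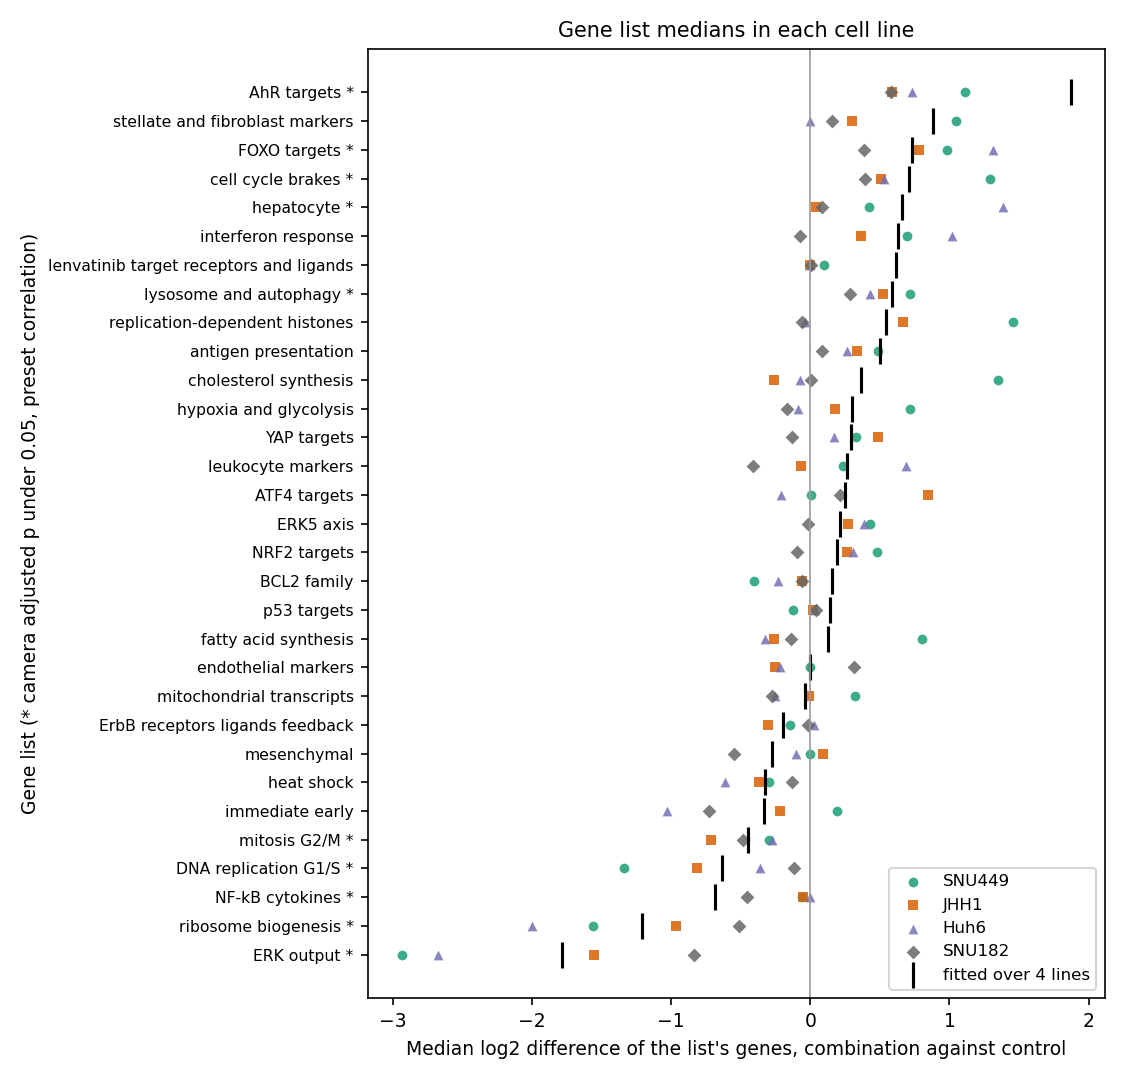
Median log2 difference between combination and control over the genes of each of the 31 lists, per cell line (coloured symbols) and for the changes fitted over all 4 lines (black ticks). The 10 lists marked with a star passed camera at the preset correlation, and 0 passed with an estimated correlation; ErbB, BCL2 family and endothelial medians change sign in limma-trend on the deposited log2 values.

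Some receptors and ligands of the drugs' pathways changed, while camera called none of their lists. ERBB3, the kinase-impaired partner of EGFR (ENSG00000065361, chromosome 12, 56079857 to 56103505), rose by 1.21 ± 0.25 and was higher in 4 of 4 lines, ERBB4 rose by 0.72 ± 0.20 and ERBB2 by 0.80 ± 0.28. The ligand EREG fell by 3.05 ± 0.66, which rested on SNU449 (-3.89) against 0.69 in Huh6, and the ligand NRG1 and the feedback inhibitor ERRFI1 fell by 0.36 ± 0.12 and 0.65 ± 0.23. EGFR itself (ENSG00000146648, chromosome 7, 55019021 to 55256620) was at 0.09 ± 0.14 (adjusted p = 0.672). Of 13 ErbB receptor, ligand and feedback genes 3 rose and 3 fell (3 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.381). Of 15 lenvatinib target receptors and ligands 4 rose and 1 fell, the same adjusted over the list alone: the FGF19 co-receptor KLB (3.16 ± 0.68), FGFR2 (1.47 ± 0.18), FGFR3 (1.18 ± 0.40), the growth factor FGF2 (0.61 ± 0.21) and the VEGF receptor FLT4 (-0.59 ± 0.19). FGFR2 was higher by 1.39 to 1.82 in 3 lines and lower, at -0.87, in SNU449, where it was near the floor. Of the 26 receptor, ligand and kinase genes fixed in advance 5 rose and 4 fell, and the other 17 lay between -1.22 (the ligand AREG, adjusted p = 0.0726) and 1.38 (KIT). PAK2 was at 0.03 ± 0.09 and MAPK7, the gene of ERK5, at 0.29 ± 0.12. Of 8 ERK5 axis genes 1 rose, also adjusted over the list alone: the ERK5 kinase MAP2K5 (0.46 ± 0.10).

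Some cell death, stress and immune genes changed, while camera called none of their lists. Of 13 BCL2 family genes 4 rose and 2 fell (4 and 4 adjusted over the list alone), with the BH3-only genes BMF at 2.29 ± 0.37, BCL2L11 at 1.31 ± 0.42, BBC3 at 0.65 ± 0.17 and BID at -0.56 ± 0.12. Of 13 antigen presentation genes 6 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.0672), with the HLA class I activator NLRC5 at 1.26 ± 0.33 and the checkpoint ligand CD274 at -1.95 ± 0.64. Of 12 interferon response genes 2 rose (1 adjusted over the list alone), IFIT1 and ISG15 (0.58 ± 0.19). Of 19 ATF4 targets 5 rose, also adjusted over the list alone, among them NUPR1 (2.20 ± 0.47) and the serine synthesis enzyme PHGDH (0.79 ± 0.14). Of 17 hypoxia and glycolysis genes 5 rose and 1 fell, the same adjusted over the list alone, with NDRG1 at 1.76 ± 0.38. Of 12 p53 targets 3 rose and 3 fell (5 and 4 adjusted over the list alone), with TP53I3 at 0.83 ± 0.24, PLK3 at -1.35 ± 0.30 and GDF15 at -1.34 ± 0.35. Of 10 heat shock genes 5 fell and 1 rose, the same adjusted over the list alone, with the chaperones HSPD1 and HSPA8 at -1.09 ± 0.21 and -0.80 ± 0.15. Of 10 NRF2 targets 2 rose, also adjusted over the list alone, with AKR1C1 at 2.29 ± 0.64, a gene with near-identical copies.

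Among lipid genes, 4 of 20 cholesterol synthesis genes rose, also adjusted over the list alone, with the regulator SREBF2 at 0.54 ± 0.16. Their median was 1.35 higher in SNU449 and -0.26, -0.07 and 0.00 in JHH1, Huh6 and SNU182. The list was not called (camera, up, adjusted p = 0.269), without SNU449 it was called downward (adjusted p = 0.0450), and without JHH1 upward (0.0190). Of 10 fatty acid synthesis genes 2 rose (2 rose and 1 fell adjusted over the list alone), with FADS2 at 0.81 ± 0.26. Of 12 YAP targets 5 rose and 1 fell, the same adjusted over the list alone, and the fall was tissue factor F3 (-1.45 ± 0.20). Of 15 mesenchymal genes 1 rose and 2 fell (1 and 1 adjusted over the list alone), with SPARC at 0.86 ± 0.22 and TNC at -1.43 ± 0.25. Of 14 immediate early genes 2 fell, also adjusted over the list alone, FOSL1 and EGR2 (-2.02 ± 0.48). Of 13 mitochondrial transcripts 2 fell (1 adjusted over the list alone), with MT-ND6, the only one encoded on the light strand, at -0.66 ± 0.10. Of 5 replication-dependent histones tested 1 rose, also adjusted over the list alone (HIST1H1C, 0.54 ± 0.15). Of other cell types' markers, 1 of 5 endothelial genes rose (VWF, 1.52 ± 0.33) and 1 fell (TIE1, -1.11 ± 0.32), 2 of 4 leukocyte genes rose (such as LCP1, 2.04 ± 0.71) and 3 of 9 stellate and fibroblast genes rose (LRAT, 1.37 ± 0.43). Adjusted over the list alone these were 1, 1, 2 and 4. Median, mean and test pointed in different directions for 4 uncalled lists: BCL2 family (median 0.159, mean 0.193, test down), p53 targets (0.142, -0.108, down), fatty acid synthesis (0.130, 0.0919, down) and endothelial markers (-0.00329, 0.0536, down). Fry, which asks only whether a list's own genes move one way, called 15 of 31 lists here: the 10 that camera called and lenvatinib targets (adjusted p = 0.0103), the ERK5 axis (0.0441), antigen presentation (0.000785), heat shock (0.0322) and stellate markers (0.0103). It called 16 for the combination against lenvatinib and 3 for the combination against gefitinib. It called 1 for gefitinib against control, and 0 for lenvatinib against control, gefitinib against lenvatinib and the departure from additivity.

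The comparison of the combination with lenvatinib asks what gefitinib adds in cells already given lenvatinib. It shares its combination libraries with the comparison above, so the results of both are not independent. ETV4 fell by 4.43 ± 1.09, SPRY4 by 3.86 ± 1.11, DUSP6 by 3.82 ± 0.80 and ETV5 by 3.09 ± 1.0. MYEOV was at -2.80 ± 0.68, GPR3 at -2.58 ± 0.72, FOSL1 at -2.49 ± 0.38, the anion transporter SLCO4A1 at -2.38 ± 0.62, the small MAF protein gene MAFF at -2.13 ± 0.41 and the vitamin D hydroxylase CYP24A1 at -2.02 ± 0.27. SERPINF2 rose by 4.09 ± 0.79, SLC23A1 by 3.68 ± 0.84, CRYAB by 3.01 ± 0.80, C10orf10 by 2.71 ± 0.71, TMEM140 by 2.64 ± 0.51 and CYP1A1 by 2.56 ± 0.57. The heme carrier HPX rose by 2.50 ± 0.55, ERP27 by 2.41 ± 0.60, the actin bundler ESPN by 2.37 ± 0.61 and BMF by 2.22 ± 0.37. ERBB3 rose by 1.17 ± 0.25, ERBB4 by 0.69 ± 0.20, FGFR2 by 1.39 ± 0.18 and KLB by 2.96 ± 0.69, and EREG fell by 2.27 ± 0.66. Of the 26 genes fixed in advance 3 rose and 1 fell, and the other 22 lay between -0.94 (AREG) and 1.05 (PDGFRB), with EGFR at 0.00 ± 0.14, PAK2 at 0.09 ± 0.09 and MAPK7 at 0.26 ± 0.12. EREG was at 0.16 without the SNU449 combination library and at 0.03 without SNU449.

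Camera called 11 of 31 lists here. Fallen genes numbered 12 of 17 for ERK output (15 adjusted over the list alone), 3 of 14 for immediate early genes (3), 13 of 25 for DNA replication (19), 12 of 20 for mitosis (14), 18 of 19 for ribosome biogenesis (19) and 5 of 10 for heat shock (5). Examples are the immediate early factors EGR2 (-2.11 ± 0.48) and EGR3 (-1.75 ± 0.52), MCM10 (-0.98 ± 0.24), RRM2 (-0.93 ± 0.16), CDC20 (-0.72 ± 0.08) and PLK1 (-0.63 ± 0.11). The nucleolar genes NOP16 and RRS1 were at -1.72 ± 0.36 and -1.51 ± 0.31, and the mitochondrial chaperones HSPD1 and HSPE1 at -0.99 ± 0.21 and -0.87 ± 0.19. Risen genes numbered 6 of 11 cell cycle brakes (8 adjusted over the list alone), 8 of 15 FOXO targets (11), 8 of 15 lysosome genes (13), 6 of 19 hepatocyte genes (8) and 3 of 5 AhR targets (5). TXNIP was at 1.42 ± 0.24, CCNG2 at 1.6 ± 0.49, KLHL24 at 2.05 ± 0.33, ULK1 at 1.15 ± 0.31, APOC3 at 3.04 ± 0.42, FGA at 2.79 ± 0.44 and AHRR at 0.76 ± 0.15. With an estimated correlation the 11 lists had adjusted p = 0.316 to 0.322. The hepatocyte call ended without Huh6 (adjusted p = 0.845), the immediate early call without SNU182 (0.0575), and the heat shock call without JHH1 (0.180) or SNU182 (0.0600).

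In total 3101 genes differed between combination and lenvatinib, 1770 higher and 1331 lower (edgeR), 566 of them at least 2-fold higher and 211 at least 2-fold lower, and 87.0% had the same sign in all 4 lines against 33.6% of tested genes. Part of that contrast again follows from the selection by the test. The count of 3101 depended on single libraries. It was 5 without the Huh6 lenvatinib library (4199 genes at an unadjusted p under 0.05), 45 without that of JHH1 and 1765 without that of SNU449. It was 1024 and 1343 without the combination libraries of Huh6 and SNU449, and 1149, 2 and 0 without the lines SNU449, JHH1 and Huh6. Without the 2 single-drug libraries of SNU449 it was 1207, and a fit of these groups alone called 2. Of 42 called named genes 7 kept the call without the JHH1 lenvatinib library and 1 without that of Huh6. Without the cell line block 0 genes were called (517 at an unadjusted p under 0.05).

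Gefitinib alone raised 4 genes, all expressed in Huh6 and close to the floor elsewhere. They were the flavin monooxygenase FMO1 (3.87 ± 0.31, adjusted p = 0.00408; ENSG00000010932, chromosome 1, 171248471 to 171285978), the steroid sulfotransferase SULT2A1 (4.13 ± 0.44, adjusted p = 0.0156; chromosome 19, 47870466 to 47886397), the intestinal alkaline phosphatase ALPI (2.78 ± 0.30; chromosome 2, 232456123 to 232460032) and the long noncoding RNA RP5-899B16.1 (4.04 ± 0.49; chromosome 6, 139854850 to 139860151). These 4 reached 1 CPM in Huh6 alone, as 1862 of the tested genes did in 1 line each, and they are named because they were the called ones, after their values were seen. Next in rank was LTBP1, which binds latent TGF-beta, at 0.54 ± 0.08 and higher in 4 of 4 lines (adjusted p = 0.0874). Among ERK output genes, 17 of 17 had values below 0, with a median of -0.98 in JHH1, -2.17 in Huh6, -0.42 in SNU182 and -0.14 in SNU449. ETV4 was at -1.81 ± 0.93 (-5.97 in Huh6, -3.77 in JHH1 and -0.02 in SNU449) and SPRY4 at -1.46 ± 0.95. Other values were EGR2 -2.52 ± 0.50, FOSL1 -1.27 ± 0.35, the ribosome assembly genes PPAN -0.92 ± 0.32 and NOP16 -0.81 ± 0.35, HSPD1 -0.55 ± 0.21, CYP1A1 2.41 ± 0.58, APOC3 2.35 ± 0.41, FGA 1.74 ± 0.42, BMF 1.35 ± 0.37 and KLHL24 1.09 ± 0.32, none past the threshold. Of the 26 genes fixed in advance 0 were called, with EGFR at -0.06 ± 0.14, ERBB3 at 0.62 ± 0.25, PAK2 at -0.06 ± 0.09, MAPK7 at 0.20 ± 0.12 and the extremes AREG (-0.75) and FGFR2 (0.83).

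Camera called 13 of 31 lists for gefitinib against control. Downward were ERK output (adjusted p = 2.53e-06), immediate early genes, DNA replication, mitosis, mesenchymal genes, heat shock, ribosome biogenesis (1.57e-11) and mitochondrial transcripts. Upward were cell cycle brakes, FOXO targets, lysosome and autophagy, hepatocyte genes and AhR targets. With an estimated correlation they had adjusted p = 0.121 (AhR) to 0.580 (DNA replication). No member passed over all genes, while 15 of 19 ribosome biogenesis genes, 4 of 10 heat shock genes and 2 of 14 immediate early genes fell adjusted over the list alone, and 3 of 19 hepatocyte, 3 of 5 AhR and 2 of 15 lysosome genes rose. Calls ended without JHH1 for DNA replication (0.0512) and brakes (0.159), without Huh6 for hepatocyte genes (0.853), and without SNU182 for immediate early (0.0558), mesenchymal (0.742) and mitochondrial lists (0.0537).

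The count of 4 rests on the tool, on the filter and on Huh6. At an unadjusted p under 0.05 there were 2136 genes. EdgeR with no filter on low counts called 24. DESeq2, also run without that filter on 32651 genes, called 31, of which 1 (RP5-899B16.1) was among the 4. Limma-voom and limma-trend called 0, and the restriction to genes at 1 CPM in all 4 lines gave a count of 0. It was 0 without the Huh6 control or gefitinib library, without JHH1 and without Huh6, 2 without SNU182, without the lenvatinib libraries of SNU449 or JHH1 or without the Huh6 combination library, 13 without the SNU449 gefitinib library, 9 without the Huh6 lenvatinib library and 8 without SNU449. Without the cell line block it was 0, with 25 at an unadjusted p under 0.05.

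For lenvatinib alone against control no gene passed. EdgeR called 0 of 16566 genes, 174 had an unadjusted p under 0.05 where 828.3 would be expected by chance, limma-voom and limma-trend called 0 and DESeq2 called 4. Fitted on these 8 libraries alone, 1429 of 14126 genes had an unadjusted p under 0.05, where 706.3 would be expected by chance, and 1 was called. A count as far under chance as 174 means that p-values of the fit over all treatments cannot be taken at face value here. Its 0 calls therefore do not show that lenvatinib changed nothing. The smallest p-values belonged to the pattern receptor TLR4 (-1.53 ± 0.33), the p38 kinase activator MAP2K6 (1.08 ± 0.29), TMEM255A (1.04 ± 0.28), B3GNT1 (0.37 ± 0.11) and the antisense RNA FBXL19-AS1 (-0.57 ± 0.17, uncertain without a stated strand setting). EGFR was at 0.08 ± 0.14, ERBB3 at 0.05 ± 0.25, FGFR2 at 0.08 ± 0.18, PAK2 at -0.06 ± 0.09 and MAPK7 at 0.03 ± 0.12, and the 26 genes fixed in advance ran from EREG (-0.77) to KIT (0.85). Camera called 4 lists downward: NF-kB cytokines (median -0.180, adjusted p = 0.00111), mitochondrial transcripts (-0.0893, 0.00029), mitosis (-0.0480, 0.0463) and ribosome biogenesis (-0.121, 0.0463). With an estimated correlation they had adjusted p = 0.106 for NF-kB and 0.867 for the other lists, and 0 members passed, also adjusted over the list alone. CXCL8 was at -1.12 ± 0.64, CXCL1 at -0.96 ± 0.59, MT-ND6 at -0.26 ± 0.10 and the spindle checkpoint gene BUB1B at -0.20 ± 0.10. Of ERK output genes, EGR1 was at 0.63 ± 0.46, with 2.30 in SNU449, and DUSP4 at -0.73 ± 0.67. The mitochondrial call ended without Huh6 (0.318), the ribosome call without SNU449 (0.344) and the mitosis call without JHH1 (0.395) or SNU182 (0.367); 3 to 7 lists were called with 1 line left out.

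The comparison of the combination with gefitinib asks what lenvatinib adds in cells already given gefitinib. EdgeR called 0 genes (2293 at an unadjusted p under 0.05), limma-voom 28, DESeq2 68 and limma-trend 0; edgeR called 20 without the SNU182 combination library, 1 without that of Huh6, 2 without Huh6 and 1 without SNU182. The lowest p-values belonged to TM4SF18 (-2.04 ± 0.31, adjusted p = 0.285), the sialic acid transporter SLC17A5 (0.56 ± 0.09), CDC20 (-0.47 ± 0.08), the collagen COL13A1 (-3.72 ± 0.67) and the kinesin KIF18B (-0.55 ± 0.10), the others with adjusted p = 0.327. SLC17A5 was higher and CDC20 and KIF18B lower in 4 of 4 lines, whereas COL13A1 rested on SNU449 (-4.41). Camera called 13 lists. Downward were ERK output (median -1.21, adjusted p = 7.82e-09), DNA replication (-0.44, 1.6e-13), mitosis (-0.29, 3.25e-13), ribosome biogenesis (-0.62, 1.14e-10) and NF-kB cytokines (-0.60, 0.0114). Upward were brakes, FOXO targets, cholesterol synthesis, lysosome and autophagy, antigen presentation, AhR targets, NRF2 targets and stellate markers, and with an estimated correlation the 13 had adjusted p = 0.281 to 0.631. Adjusted over the list alone, 12 of 20 mitosis, 10 of 19 ribosome biogenesis, 9 of 17 ERK output, 4 of 25 DNA replication and 1 of 14 NF-kB genes fell and 2 of 5 AhR genes rose. Values were DUSP6 -2.78 ± 0.80, ETV4 -2.80 ± 1.08, MCM10 -0.64 ± 0.24, CCNE2 -0.69 ± 0.17, CCNA2 -0.47 ± 0.10, NOP16 -1.04 ± 0.36, CCNG2 1.09 ± 0.49, BCL2L11 1.06 ± 0.42, IFIT1 2.05 ± 0.44, CYP1B1 1.74 ± 0.60, AKR1C1 1.80 ± 0.63, CXCL8 -1.64 ± 0.72, CCL2 -1.38 ± 0.30 and KLB 1.6 ± 0.60. EGFR was at 0.15 ± 0.14, ERBB3 at 0.59 ± 0.24, FGFR2 at 0.64 ± 0.17, PAK2 at 0.09 ± 0.09 and MAPK7 at 0.09 ± 0.12, and the 26 fixed genes ran from EREG (-2.56) to PDGFRB (0.83). Much of this lay in SNU449: DUSP6 differed by -5.39 there and by -1.38, -3.25 and -1.47 in JHH1, Huh6 and SNU182, and CCNG2 by 3.26 against 0.16 to 0.35. Without SNU449 the cholesterol list was called downward (0.0385) and the NRF2 (0.120) and stellate (0.177) calls ended. Without Huh6 the AhR (0.138) and NF-kB (0.0506) calls ended, and without JHH1 (0.0623) or SNU182 (0.0709) the stellate call did.

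Set directly against lenvatinib, gefitinib raised 4 genes: FMO1 (4.08 ± 0.32, adjusted p = 0.00299), SULT2A1 (4.76 ± 0.46), RP5-899B16.1 (3.60 ± 0.47) and ALPI (2.71 ± 0.30). All were named after their values were seen, and this comparison shares the gefitinib libraries with the one above. The glucose transporter family member SLC5A9 came next (2.29 ± 0.37, adjusted p = 0.124). EGFR was at -0.14 ± 0.14, PAK2 at 0.00 ± 0.09, MAPK7 at 0.17 ± 0.12, and the 26 fixed genes ran from AREG (-0.48) to FGFR2 (0.75). Camera called 10 lists: ERK output (median -0.72, adjusted p = 1.87e-05), immediate early (-0.65), DNA replication (-0.14), mitosis (-0.06), heat shock (-0.22) and ribosome biogenesis (-0.48) lower, and FOXO (0.38), lysosome (0.22), hepatocyte (0.48) and AhR (0.38) genes higher after gefitinib. With an estimated correlation they had adjusted p = 0.271 to 0.645. Without Huh6 the hepatocyte list was called the other way (0.0443), and 6 of the 10 calls were lost or turned without 1 line. At an unadjusted p under 0.05 there were 1214 genes, and edgeR with no filter on low counts called 41. DESeq2, also without that filter, called 20, of which 0 were among the 4 named, and limma-voom and limma-trend called 0. Without single libraries the count went from 0 (the Huh6 gefitinib or lenvatinib library) to 8 (the SNU449 gefitinib library), with 2 without the controls of SNU449 or JHH1 or their lenvatinib libraries, and 1 and 0 without JHH1 and Huh6.

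After both drugs, ERK output genes such as DUSP6 and ETV4 had values below the sum of the single-drug changes, but no single gene passed. EdgeR called 0 genes for the departure from additivity, limma-voom and limma-trend 0 and DESeq2 7, and edgeR called 1 without the SNU182 combination library. At an unadjusted p under 0.05 there were 329 genes, where 828.3 would be expected by chance, so 0 calls do not show that the drugs add up. Camera called ERK output (median departure -1.11, adjusted p = 4.12e-10), DNA replication (-0.40), mitosis (-0.24) and ribosome biogenesis (-0.50) as below additive, and brakes (0.44), FOXO targets (0.41), lysosome (0.22) and mitochondrial transcripts (0.18) as above, with adjusted p = 0.507 to 0.646 with an estimated correlation. Fry called 0 of 31 lists (0.681 for ERK output), and no member passed adjusted over the list alone. The ERK output median departed by -2.32 in SNU449, -0.65 in JHH1, -1.03 in Huh6 and -0.31 in SNU182. DUSP6 departed by -2.53 ± 1.01, ETV4 by -2.61 ± 1.35, NOP16 by -0.91 ± 0.49, the replication licensing factor CDT1 by -0.63 ± 0.26 and CDC20 by -0.44 ± 0.12, and CCNG2 by 0.94 ± 0.67, KLHL24 by 0.96 ± 0.46 and BCL2L11 by 0.96 ± 0.58. EGFR, PAK2 and MAPK7 departed by 0.06 ± 0.20, 0.15 ± 0.12 and 0.06 ± 0.17. Without SNU449 the calls of brakes (0.0679) and lysosome (0.197) ended, and without JHH1 (0.0557) or Huh6 (0.610) that of mitochondrial transcripts. Leaving out the 2 single-drug libraries of SNU449 ended the calls of FOXO targets (0.110), brakes (0.0789) and lysosome (0.242).

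The lines answered differently. Gefitinib alone changed 1931 of 13609 genes at least 2-fold in Huh6, 332 in JHH1, 275 in SNU182 and 133 in SNU449. Lenvatinib alone changed 363 in SNU449, 177 in Huh6, 172 in JHH1 and 159 in SNU182, and the combination changed 2628 in SNU449, 2739 in Huh6, 920 in JHH1 and 509 in SNU182. Taking the drugs as additive within each line, edgeR called 6830 genes for gefitinib in Huh6 (3994 higher and 2836 lower), 276 in JHH1 (195 and 81), 24 in SNU182 (15 and 9) and 23 in SNU449 (23 and 0). Lenvatinib called 2204 genes in SNU449 (1321 higher and 883 lower) and 0 in JHH1, Huh6 and SNU182, where 649, 574 and 474 had an unadjusted p under 0.05 and limma-voom called 0. Chance would give 828.3 of 16566 genes, so the p-values in JHH1, Huh6 and SNU182 cannot be taken at face value. The 0 calls do not show that lenvatinib changed nothing in these lines. At an unadjusted p under 0.05 gefitinib had 8189 genes in Huh6, 3901 in SNU449, 3878 in JHH1 and 1778 in SNU182. In SNU449 lenvatinib had 5534, a smaller contrast with gefitinib than the called counts give. With no filter on low counts gefitinib called 2470, 2205 and 542 in SNU449, JHH1 and SNU182 and lenvatinib 3950, 78, 45 and 16 in SNU449, JHH1, Huh6 and SNU182; limma-voom called 10 and 70 for gefitinib in SNU449 and SNU182. With the single-drug labels of SNU449 exchanged, gefitinib called 2204 there and lenvatinib 23. In SNU449 the combination departed from additivity, with 1491 genes at least 2-fold off the sum, so its line effects mix each drug alone with its effect beside the other. The gefitinib effect differed between lines for 1745 genes (4369 with no filter). Those with the smallest adjusted p stood out in Huh6: the iron regulator ligand BMP6 (-5.22 ± 0.18, adjusted p = 0.000167; chromosome 6, 7726797 to 7881422), nicotinamide methyltransferase NNMT (-4.33 ± 0.22), the stress response gene IER3 (-4.32 ± 0.21), GPRC5A (-3.40 ± 0.18), the retinoid carrier CRABP2 (-2.80 ± 0.14), ephrin EFNB2 (-2.61 ± 0.12) and TAGLN2 (-1.62 ± 0.09). SAMHD1, a dNTP hydrolase, was at 2.74 ± 0.13, the ascorbate transporter SLC23A2 at 1.87 ± 0.09 and the sulfate transporter SLC26A2 at 1.39 ± 0.12, the latter at -1.77 ± 0.13 in JHH1. All but BMP6 had an adjusted p of 0.000509.

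The lenvatinib effect differed between lines for 6 genes, for 1 in limma-voom, 0 with the single-drug labels of SNU449 exchanged (edgeR) and 1514 with no filter. The collagenase MMP1 was at -4.73 ± 0.24 in SNU449 (adjusted p = 0.00786; chromosome 11, 102789920 to 102798160) and between -0.20 and -0.11 elsewhere. The folate enzyme ALDH1L1 was at 3.65 ± 0.27, the pyridoxal kinase PDXK at 1.34 ± 0.09 and PPME1 at 1.32 ± 0.10 in SNU449, and the sialyltransferase ST3GAL1 was at -1.58 ± 0.13 in SNU449 and 2.07 ± 0.45 in Huh6. The adjusted p was 0.0362 for ALDH1L1, PDXK, PPME1 and ST3GAL1.

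**Figure D3:**
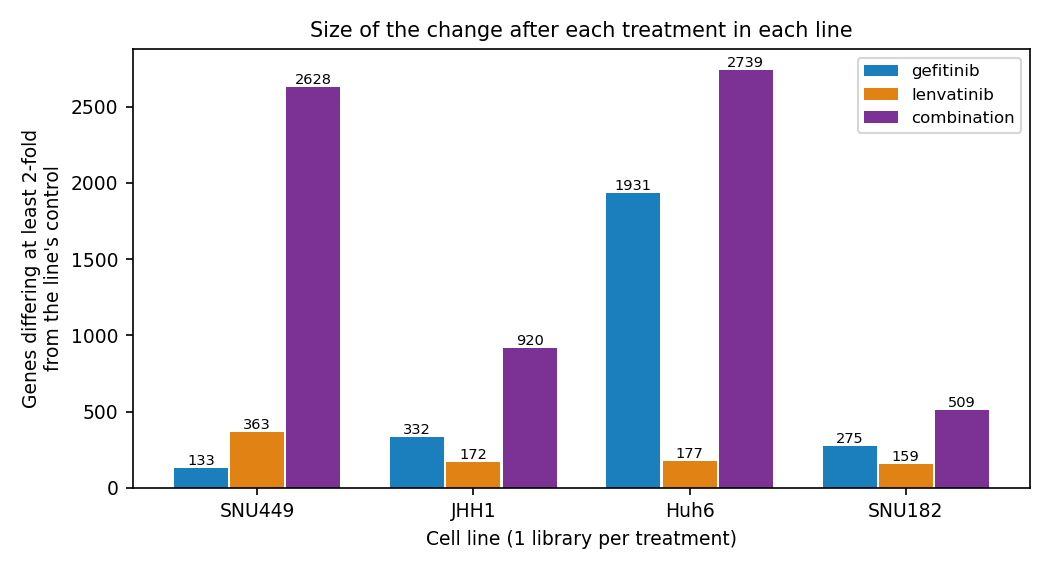
Number of genes, of 13609, whose log2 CPM differs from the line's own control by at least 1, for each treatment in each cell line (bars, 1 library per treatment). SNU449 shows 133 and 363 for the single drugs and 2628 for the combination, and Huh6 1931 for gefitinib and 2739 for the combination.

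Gefitinib's effect can be measured in 2 ways from separate libraries, without lenvatinib (gefitinib against control) and with it (combination against lenvatinib), and both estimates followed each other across genes. Over 16566 genes Pearson's r was 0.807, Spearman's rho 0.781 and the slope 1.16. Over 10843 genes with a mean log2 CPM of at least 3, r was 0.893 and the slope 1.42. Of the genes called higher with lenvatinib present, 99.2% were above 0 without it, and of those called lower, 99.2% were below 0. All 4 genes called without lenvatinib were among the 1770 called higher with it, where independent lists would share 0.427. For lenvatinib the corresponding r was 0.355, rho 0.367 and the slope 0.570. Over the higher-expressed genes its r was 0.508 and the slope 1.17. Lenvatinib had 0 calls on either side in edgeR (174 and 2293 at an unadjusted p under 0.05). By line, over the 10843 genes, gefitinib's r was 0.381 in SNU449, 0.729 in JHH1, 0.919 in Huh6 and 0.630 in SNU182, and lenvatinib's 0.592, 0.208, 0.00625 and 0.283.

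**Figure D4:**
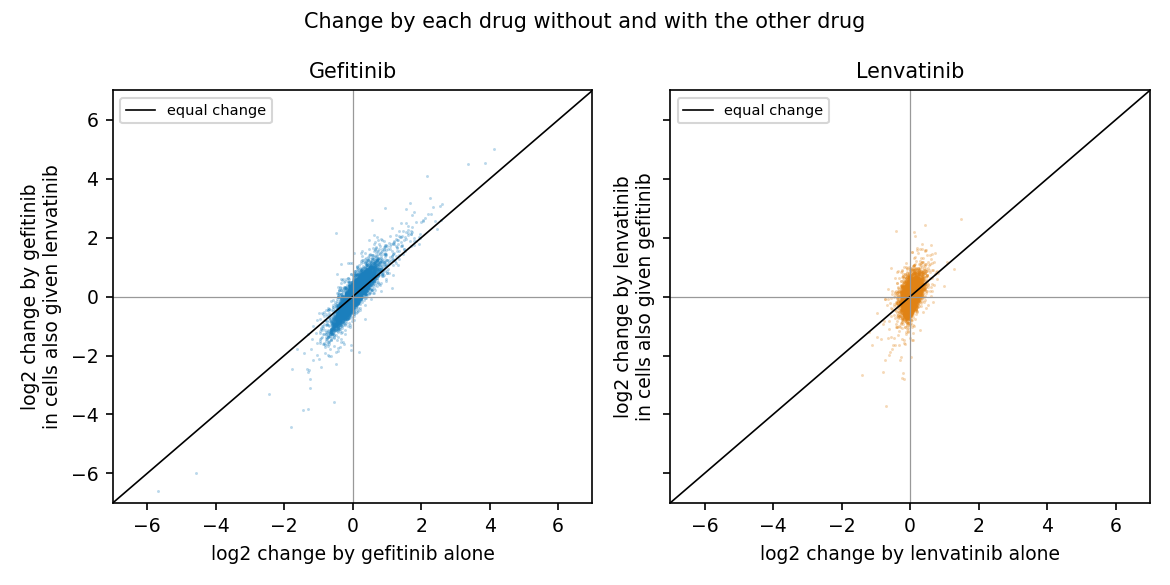
Fitted log2 change of each of 10843 genes by a drug alone (horizontal) and by the same drug in cells also given the other drug (vertical), for gefitinib (left) and lenvatinib (right), with the line of equal change. Gefitinib points have a slope of 1.42 and r of 0.893, and lenvatinib points a slope of 1.17 and r of 0.508.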

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

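The tests of technical and biological explanations and the counts over other splits of the samples were chosen after the results were seen; the search for lines that stand apart and the tests of differences between lines were not. A value was singled out where 1 of the 4 lines lay far from the other 3, which happens by chance in about 1 of 20 groups of values. Of 270 groups of values 33 were singled out, where chance would give 13.5: 0 of 16 for library measures, 4 of 7 for numbers of 2-fold changes, 6 of 31 for list medians and 23 of 216 for genes. Lists and genes within a line move together, so these groups are not independent.

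SNU449 differed 2-fold between combination and gefitinib for 2052 genes, far above the other lines, and its medians of cell cycle brakes (1.29), cholesterol synthesis (1.35) and fatty acid synthesis (0.80) after the combination stood above theirs. A control library exchanged with a single-drug library would make a drug's change alone oppose its change beside the other drug; both correlations across genes were above 0, the lower at 0.381, which argues against that exchange. Depth is argued against as well, since at an equal depth of 11321037 counts 1513 genes departed at least 2-fold from additivity in SNU449 and 572 in Huh6, the next line. A biological explanation, that ERK in SNU449 takes input from receptors of both drugs so that either alone leaves it running, needs ERK output below the sum of both drugs. Its median departed by -2.32, but that follows from the medians already described and tests nothing further, so this explanation and a one-off difference in a culture both stay open.

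In SNU449 lenvatinib alone changed 363 genes 2-fold, more than in any other line and more than gefitinib did there. Were the labels of its gefitinib and lenvatinib libraries exchanged, the difference between these libraries should run opposite to that in the other lines. Over 3322 genes that the combination left within 0.25 in SNU449, the correlation with the mean of the other lines was 0.0307, where the other lines had 0.234, 0.237 and 0.193 with each other. These genes were chosen by the response of SNU449 alone, which can itself bring its value near 0, so the 0.0307 decides nothing. Over all 10843 genes the correlation was -0.160 against 0.402, 0.388 and 0.265. In SNU449 the median of 5 AhR targets, higher after gefitinib than lenvatinib in the other 3 lines, was 0.537 after gefitinib and 0.0601 after lenvatinib, as the labels say, whereas that of ERK output was -0.14 and -0.51, the other way round from those lines. An exchange and a line that answers lenvatinib more than gefitinib cannot be told apart here. Either could turn the difference against that of the other lines, and each treatment has 1 library.

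Families of protein production fell with the combination: 167 of 316 genes in 7 families, from cytosolic ribosomal proteins to nucleoporins, with 4 risen. Cytosolic ribosomal protein medians were uneven, at -0.57 in SNU449 and -0.56 in Huh6 but -0.08 in JHH1 and -0.02 in SNU182. Proteasome subunits were more even, at -0.38, -0.23, -0.26 and -0.24 in the same order. Of the 7 families, 7 lay below random sets matched on mean expression, and 7 below random sets matched on gene span. Random genes of like expression or like span, each matched alone, thus did not fall as far. How unusual the falls are stays undecided, as the families were chosen after the data were seen. Genes of a family may also move together, unlike those of random sets. Camera's lowest adjusted p was 0.311 with an estimated correlation over 24 families. No biological explanation was tested for this pattern, and reads shared with the many ribosomal protein pseudogenes stay open for that family.

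Parting the samples differently while keeping all 4 lines in both groups, the gefitinib libraries against control gave the real count of 4 in 1 of 8 splits (highest other 3), the combination against control 1 of 8 (4848, highest other 9), the combination against lenvatinib 1 of 8 (3101, highest other 9) and gefitinib against lenvatinib 1 of 8 (4, highest other 3). For lenvatinib against control 8 of 8 splits gave as many as the real 0 (highest other 0), for the combination against gefitinib 8 of 8 (0, highest other 0) and for the departure from additivity 60 of 60 (0, highest other 54). The 8 splits are too few for a share under 0.05, and beside a real count of 0 every split gives as many, so those 3 counts decide nothing. Among all 35 splits the highest other counts were 14, 110, 19, 23, 2846 and 11 for gefitinib, lenvatinib and the combination against control, the combination against lenvatinib and gefitinib, and gefitinib against lenvatinib. The 2846, and the 110 beside a real 0, came from splits that put both libraries of some line in 1 group. How the lines differ in response can then enter the count, so these values do not measure chance. No further cause was tested.

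Other values standing apart in 1 line are these. Gefitinib changed 1931 genes 2-fold against control and 2026 against lenvatinib in Huh6. After the combination, SNU449 medians were 0.10 for lenvatinib targets and -0.12 for p53 targets, and SNU182 had -0.45 for NF-kB cytokines. Against control the combination gave CIDEB 4.39 in Huh6 and CCNA2 -1.04 in JHH1, and in SNU449 PIK3IP1 4.66, CYP1B1 3.55, ISG15 1.34, ERBB4 1.26 and FGFR2 -0.87. Against lenvatinib it gave FGFR2 -0.61 in SNU449, and against gefitinib COL13A1 -4.41, CCNG2 3.26, BCL2L11 2.90, CYP1B1 2.98 and AKR1C1 3.45 there. Gefitinib against control gave FMO1 3.83, SULT2A1 4.21 and APOC3 2.49 in Huh6 and FGFR2 -0.87 in SNU449, and against lenvatinib FMO1 4.03 and SULT2A1 4.76 in Huh6 and PAK2 -0.0411 in SNU449. Lenvatinib against control gave EGR1 2.30 in SNU449, and the departure from additivity there was 2.83 for CCNG2 and 2.30 for BCL2L11.

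A test of the difference itself singled out the drug effects that vary between lines: 1745 genes for gefitinib (4369 with no filter on low counts) and 6 for lenvatinib (1 in limma-voom, 0 in edgeR with the SNU449 labels exchanged, 1514 with no filter). For gefitinib the adjusted p was 0.000167 for BMP6 and 0.000509 for NNMT, SLC23A2, EFNB2, CRABP2, GPRC5A, SAMHD1, IER3, SLC26A2 and TAGLN2. For lenvatinib it was 0.00786 for MMP1 and 0.0362 for ALDH1L1, PDXK, ST3GAL1 and PPME1.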

How the results depend on the processing

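The restriction to genes at 1 CPM in all 4 lines, leaving out the SNU449 single-drug libraries and exchanging their labels were chosen after the results were seen; the other tests were planned. The counts for the combination against control (4848) and lenvatinib (3101) stayed within 1.5 times under DESeq2, limma-voom, limma-trend, other size factors, no filter and 1 CPM in all 4 lines, from 4139 to 5084 and from 2567 to 3642. With no replicate block, gefitinib against control, combination against control, combination against lenvatinib and gefitinib against lenvatinib gave 0 genes each, as the lines then enter the spread, and the list tests gave 8 for the combination against gefitinib and 2 for lenvatinib against control. With no filter on low counts gefitinib against control gave 24, combination against gefitinib 2 and gefitinib against lenvatinib 41. In the line models no filter gave 4369 genes for the gefitinib difference between lines and 2470, 2205 and 542 within SNU449, JHH1 and SNU182, and for lenvatinib 1514 between lines and 3950, 78, 45 and 16 within SNU449, JHH1, Huh6 and SNU182. DESeq2 gave 31 for gefitinib and 4 for lenvatinib against control, 68 for the combination against gefitinib, 20 for gefitinib against lenvatinib and 7 for additivity. Limma-voom gave 0 for gefitinib against control, 28 for the combination against gefitinib, 0 for gefitinib against lenvatinib, 10 and 70 for gefitinib within SNU449 and SNU182, and 1 for the lenvatinib difference between lines. Limma-trend and 1 CPM in all 4 lines gave 0 for gefitinib against control and against lenvatinib. Only the 2 groups compared gave 0 for gefitinib against control and against lenvatinib, 1 for lenvatinib and 1 for the combination against control, and 2 for the combination against lenvatinib. These fits have fewer samples and a spread of their own. At an unadjusted p under 0.05 they gave 4053 of 14314 genes for the combination against control, where the main fit gave 7077 of 16566. For lenvatinib against control they gave 1429 of 14126, where the main fit gave 174. Counts of the main fit thus rest on a spread shared by all 4 treatments. Without the SNU449 single-drug libraries gefitinib against control gave 7, the combination against lenvatinib 1207 and the list tests of lenvatinib 11. With these labels exchanged gefitinib gave 2 against control and 2 against lenvatinib, 2204 within SNU449 and, for lenvatinib, 23 within SNU449 and 0 between lines, with 7 lists for lenvatinib. A correlation estimated per list gave 0 lists in all 7 comparisons.

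Leaving out a library or line, counts ran from 0 to 13 for gefitinib and 1701 to 5694 for the combination against control, 0 to 4446 for the combination against lenvatinib, 0 to 20 against gefitinib, 0 to 8 for gefitinib against lenvatinib, 0 to 1 for additivity, and 3 to 7 lists for lenvatinib. Reversed were cholesterol synthesis without replicate 1 (combination against control, adjusted p 0.0450, otherwise 0.0190 to 0.26 without a line; against gefitinib, 0.0385, otherwise 0.00142 to 0.0449), the hepatocyte list without replicate 3 (gefitinib against lenvatinib, 0.0443, otherwise from 1.29e-11), and EREG in the combination against lenvatinib, at 0.16 without combination replicate 1, 0.03 without replicate 1 and otherwise down to -2.94. Except where named, the cause was not tested. At 11321037 to 17664695 counts, a 1.5-fold change was recovered for 8 of 50 simulated genes for the combination against control, with the change the same in all lines.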

Other observations

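The gene families, the cholesterol synthesis values and the gene span values in this part were all chosen after the data had been seen. Beyond the lists fixed in advance, 167 of 316 genes in 7 families for making and handling proteins fell with the combination, and 4 rose. Among cytosolic ribosomal proteins 34 of 82 fell and 0 rose, among mitochondrial ribosomal proteins 42 of 78 fell and 1 rose, among translation initiation factors 24 of 52 fell, among RNA polymerase subunits 16 of 28, among CCT chaperonin subunits 8 of 9, among proteasome genes 28 of 47 and among nucleoporins 15 of 20. Named members, picked after their values were seen, were POLR3G (-1.86 ± 0.33), a subunit of RNA polymerase III, POLR1B of RNA polymerase I (-1.14 ± 0.24), RPL22L1 (-1.15 ± 0.34), RPL36A (-1.06 ± 0.20), MRPS2 (-0.94 ± 0.18) and MRPL3 (-0.87 ± 0.15). Others were EIF5A (-1.03 ± 0.20), EIF4A1 (-0.88 ± 0.23), CCT5 (-0.91 ± 0.17), the proteasome assembly chaperone PSMG1 (-0.84 ± 0.17), NUP35 (-0.93 ± 0.17) and NUP155 (-0.79 ± 0.15). PSME1, the interferon-inducible proteasome activator, rose by 0.64 ± 0.15. The 7 family medians lay between -0.63 and -0.28, and camera's adjusted p ran from 3.06e-15 (cytosolic ribosomal proteins) to 7.3e-05 (CCT subunits), with a lowest adjusted p = 0.311 with an estimated correlation over 24 families. None of these 7 medians turned positive over 31 settings, the highest being -0.23.

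Other families held more risen than fallen genes, where 2805 of all 16566 tested genes rose and 2043 fell. Of 63 RAB GTPases 21 rose and 1 fell (camera adjusted p = 0.00863), and of 18 apolipoproteins 7 rose (0.00205). Of 277 solute carriers 61 rose and 23 fell (0.0499), of 19 serpins 8 rose and 2 fell (0.0388), and of 39 collagens 8 rose and 3 fell (0.0601, not called). Respiratory chain families stayed near 0: the median was -0.03 over 44 NDUF subunits, of which 9 fell (camera, down, adjusted p = 0.0456), and 0.04 over 22 cytochrome c oxidase subunits, of which 1 fell. Of 37 HOX genes 5 fell and 1 rose, with a median of -0.93 in Huh6 and, for the fit without replicate 3, 0.02. With an estimated correlation these had adjusted p = 0.311 (RAB GTPases, apolipoproteins, solute carriers, serpins and collagens), 0.397 (NDUF) and 0.427 (HOX).

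In SNU449 the cholesterol pathway stood out in CPM as well. HMGCS1 was at 63.8 in control, 91.7 with gefitinib, 89.2 with lenvatinib and 242 with both, and INSIG1 was at 29.0, 37.4, 36.0 and 108. The list's median difference from control there was 0.285 for lenvatinib, 0.328 for gefitinib and 1.35 for both. Taking the drugs as additive, the fitted median was 0.68 for lenvatinib, with 14 of 20 genes called, and 0.70 for gefitinib, with 1 called; this fit takes up the combination's effect in the line that departs most from additivity.

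Across 10596 genes the combination's change correlated weakly with the genomic span of the gene (Spearman's rho 0.125; 0.0899, 0.156, 0.127 and -0.0238 in SNU449, JHH1, Huh6 and SNU182). Among the 2649 genes of shortest span 452 rose and 566 fell, and among the 2649 of longest span 561 rose and 255 fell. By annotation, 90 of 701 antisense RNAs rose and 26 fell, 87 of 788 long intergenic RNAs rose and 23 fell, and 2546 of 14151 protein-coding genes rose and 1953 fell; antisense counts are uncertain without a stated strand setting.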
